A study of Serinus canaria with 18 samples.

How the data were processed

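Poly(A) RNA from the liver and spleen of domestic canaries (Serinus canaria) was measured by RNA sequencing in 18 libraries, 3 per treatment in each tissue. Per the labels' protocols, total RNA was isolated with a column kit that included proteinase K and DNase I steps, and libraries were made with the NEBNext Ultra kit. Tissue had been kept in RNAlater, per the series' design text. The authors deposited a table of counts, whole numbers of reads per gene that are not normalised, with gene names, scaffold positions, biotypes and descriptions beside them. CASAVA 1.8, HISAT2 and HTSeq 0.6.1 are named in the submitters' processing notes, without their settings. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. Reads shared between near-identical genes, overlapping genes or antisense partners could therefore have been split or lost in ways that the counts do not show, so values of gene families such as the metallothioneins, the IFIT genes and the "-like" loci are uncertain in that respect.

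The table held 17393 genes, of which 795 had no count in any library. Total counts ran from 13030732 to 20099270 per library. Gene names were those of the table. Of 4867 genes with only a locus number, 3290 were found by that number in a RefSeq gene table of the assembly serCan2020 and 397 received a symbol from it; no coordinate was taken from that table. Positions printed are those of the deposited table, whose build is not named in the sources used here. No pair of replicates was a repeat of the same library: the mean chi-square per gene between replicates, which is near 1 for sampling noise alone, was at least 45.4.

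The labels do not give the sex of the birds. It was read from 24 genes chosen because each had at most 3 counts in some libraries and was present in all others. This is the pattern of genes on the female-specific W chromosome. Their total was at most 2 counts in the former and at least 11357 in the latter. Beside it stands a scaffold that held all 10 of 10 known avian Z genes looked up and 851 genes in all.

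Groups were taken from the treatment and tissue labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. For each tissue, genes were filtered with filterByExpr, scaled by TMM and fitted with edgeR's robust quasi-likelihood model over all 9 libraries, and each pair of treatments was tested with glmQLFTest. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. Whether a response differed between the tissues was tested as an interaction in a fit over all 18 libraries. Adjusted p-values of genes are edgeR's unless another tool is named. Standard errors of log2 fold changes are approximate, taken as the size of the fold change over the square root of F. Levels are TMM-scaled CPM, counts relative to the library total, given as mean ± SD over 3 libraries. Only the summed yolk precursor levels are CPM without TMM scaling.

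Lists of genes for 26 pathways and cell types, the comparisons, the tests, most alternatives and the rule for named genes were fixed before the data were examined. A list with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; 24 lists were tested in liver and 23 in spleen. Camera with a correlation estimated per list and fry were run beside it, the latter asking whether the members move, on balance, in a single direction, with no comparison to other genes. No list call held with an estimated correlation in any of the 6 comparisons within a tissue. Fry called only the interferon-stimulated list between watching and infected birds, in both tissues, and the antigen presentation list in both liver comparisons with infected birds. The interferon-stimulated list in infected birds against controls was not called by fry (adjusted p = 0.0854 in spleen and 0.0598 in liver). Nor was the proliferation list in any comparison. List members were matched by symbol. The named genes were the 10 highest and 10 lowest called fold changes with separate groups, a symbol and a mean log2 CPM of at least 1; up to 2 called members per direction of each called list, or else the 2 members of smallest p as values; the genes of smallest p, up to 10, where fewer than 10 were called; and C3, C9, CFB, SAA, FGB, IL1B, IL10, MX1, CD3E, PAX5, MARCO, FKBP5 and MKI67, of which those that matter to a comparison are printed. Some genes that the rule names are not reported here. Genes outside this rule are said to be chosen after their values were seen.

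The shared response of the watching and infected birds was measured as the correlation and the covariance of their log2 fold changes with a prior count of 2. Beside it stand 100 simulations of unchanged groups with common controls, in which all libraries, controls included, were drawn anew and each gene on its own. The procedure was tested on simulated counts with genes changed by known amounts. The genes of lowest mean level were left out of the changed genes, so the shares recovered hold only for better expressed genes. In spleen, 52% of genes changed by 1 on the log2 scale and 93% of those changed by 2 were recovered for the watching birds against controls over 13437 genes, and 59% and 95% for the watching against the infected birds. In liver the shares were 0% and 5% for the watching birds against controls and 0% and 16% against infected birds, over 12392 genes. For the interaction of the watching birds, 0% and 14% were recovered over 14050 genes. False calls made up at most 6.7% of the calls in these simulated counts. Here too each gene was drawn on its own. The shares recovered and of false calls therefore leave out variation that genes share, and may not hold for the real libraries. Infected birds against controls were not simulated.

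Alternatives covered the scaling, filter, test, model, covariates, thresholds, list members and libraries used. Intervals and spreads describe only these libraries.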

Results

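RNA was sequenced from the liver and spleen of domestic canaries, a songbird, to ask how seeing sick birds affects gene expression. One group (MG_OBS, libraries 1 to 3) had watched canaries with a conjunctival infection by the bacterium Mycoplasma gallisepticum for 5 to 6 days, and the controls (CONT, libraries 4 to 6) had watched control canaries for as long. A further group (MG, libraries 7 to 9) consisted of infected canaries, collected for comparison. Each group had 3 libraries per tissue. Liver libraries held 14353707 to 18946979 counts and spleen libraries 13030732 to 20099270. The labels do not say that the libraries came from separate birds, so p-values measure only the spread between these samples, which may be partly technical.

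The infected group differed from the others in sex. Both tissues of MG replicates 7 and 9 held at most 2 counts over 24 genes with a W chromosome pattern, against at least 11357 in every other library. These genes were chosen for that pattern, so the gap alone is no test. Genes of the Z scaffold, relative to each gene's median over the tissue, lay above other genes in MG 7 and 9. The log2 difference was 0.43 and 0.38 in liver and 0.57 and 0.73 in spleen. In every other library it was 0 or below. MG 7 and 9 were therefore read as male and all other libraries as female. All males were thus in MG. A fit with sex as a covariate therefore rests on the female MG 8 for infection, as does leaving out MG 7 and 9. These are close to the same comparison, with a single MG library per tissue, and cannot tell sex from that library. The liver libraries also differed in their share of haemoglobin transcripts. Haemoglobin genes took 11.6% of counts in liver MG_OBS 1, 5.09% in liver MG 8, 3.05% in liver CONT 4 and at most 2.23% in the other 6 livers. In spleen they took 0.357% to 2.09%. Mitochondrial genes took 11.5% to 33.0% of liver counts and 1.19% to 1.86% of spleen counts.

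**Figure D1:**
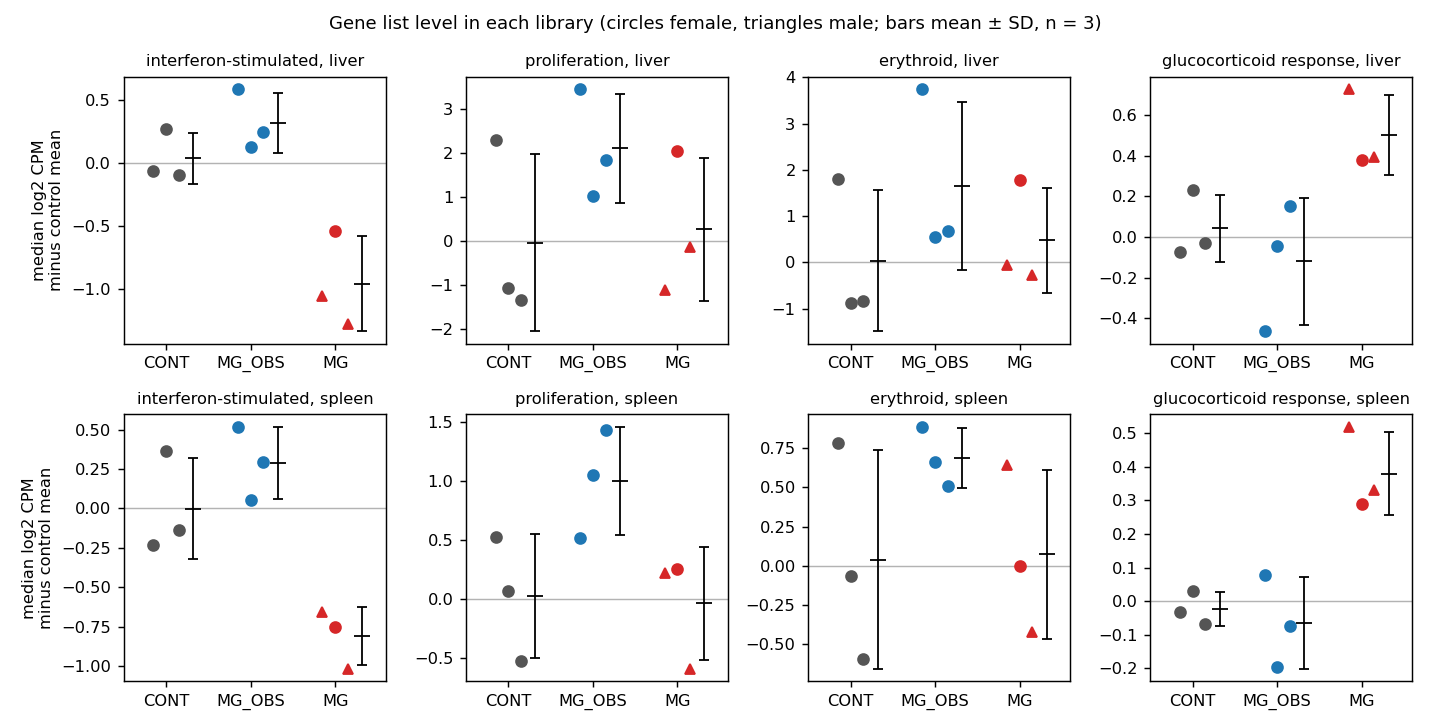
Level of 4 gene lists in each library, as the median over list members of log2 CPM minus the control mean (vertical axis, log2), by treatment; circles are female, triangles male, and bars are mean ± SD (n = 3). Interferon-stimulated genes lay at -0.96 ± 0.38 in MG livers and -0.81 ± 0.19 in MG spleens, below every library of the other groups, and proliferation genes lay at 1.002 ± 0.46 in MG_OBS spleens against 0.02 ± 0.53 in controls.

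In the spleens of watching birds, genes of cell division rose together against controls. All 32 measured proliferation genes had positive log2 fold changes, with a median of 0.99 (camera adjusted p = 9.12e-34; adjusted p = 0.599 with an estimated correlation). None of them passed over all genes, and 26 were higher when adjusted over the list alone. CDC20, an activator of the complex that starts anaphase, had 68.9 ± 7.97 CPM against 31.6 ± 12.6 in controls (SD, n = 3; log2 fold change 1.13 ± 0.27 SE), and the replication helicase subunit MCM2 had 127 ± 35.4 against 71.7 ± 13.3. MKI67, the gene of the proliferation antigen Ki-67, had 280.0 ± 118 against 121 ± 32.3.

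Cholesterol synthesis genes rose as a list in the same spleens, with 19 of 20 members positive and a median of 0.46 (camera adjusted p = 7.43e-07; adjusted p = 0.599 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. SQLE, squalene epoxidase, had a log2 fold change of 0.92 ± 0.30 and 78.5 ± 29.3 CPM against 41.4 ± 11.5. The median fell to 0.21 without MG_OBS 3, still past the threshold. The 73 ribosomal protein genes fell slightly, with a median of -0.17 (camera adjusted p = 2.38e-09; adjusted p = 0.599 with an estimated correlation) and -0.11 without MG_OBS 1, and no member passed, over all genes or adjusted over the list alone. Erythroid genes rose as a list too, with no member past the test over all genes or adjusted over the list alone: the median of the 17 was 0.50 (camera adjusted p = 0.00536; adjusted p = 0.599 with an estimated correlation), but the call was lost without MG_OBS 1 (0.32, adjusted p = 0.124) and CONT 6 (0.20, adjusted p = 0.264), and the median was 1.05 without CONT 4 and 0.33 without CONT 5. Thrombocyte genes also rose, 10 of 11 positive with a median of 0.65 (camera adjusted p = 0.00219; adjusted p = 0.599 with an estimated correlation) and none past the test over all genes or adjusted over the list alone. That call was lost without MG_OBS 1 (0.002, adjusted p = 0.901) and CONT 5 (0.60, adjusted p = 0.0524), and the median was 1.0 without MG_OBS 2. Across the watching spleens alone these lists did not follow the proliferation list. Its level was 0.52, 1.05 and 1.43 in MG_OBS 1 to 3, against 1.67, -0.06 and 0.09 for thrombocyte and 0.89, 0.66 and 0.51 for erythroid genes. Leaving out the control CONT 6, however, gave the lowest median of both the erythroid list (0.20) and the proliferation list (0.76). Erythroid precursors therefore stay open as a source of the proliferation genes.

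Interferon-stimulated genes rose in watching spleens with a median of 0.27 in 18 members (camera adjusted p = 1.31e-04; adjusted p = 0.599 with an estimated correlation), none of them past the test, over all genes or adjusted over the list alone. This interferon call was lost without MG_OBS 1 (median 0.17, adjusted p = 0.112) and without CONT 4 (0.17, adjusted p = 0.0612). Without CONT 5 the median was 0.48. T and NK cell genes rose in the same spleens, 16 of 23 positive with a median of 0.20 (camera adjusted p = 0.00875; adjusted p = 0.599 with an estimated correlation) and none past the test over all genes or adjusted over the list alone. That call was lost without MG_OBS 1 (0.15, adjusted p = 0.27) and CONT 5 (0.01, adjusted p = 0.504). The T and NK cell median was 0.30 without MG_OBS 2 and 0.48 without CONT 6. Inflammatory cytokine and NF-kB genes fell with a median of -0.28 in 24 members (camera adjusted p = 8.46e-04; adjusted p = 0.599 with an estimated correlation), a call lost without CONT 5 (-0.19, adjusted p = 0.217). No member of that list passed, over all genes or adjusted over the list alone; TNFAIP3, an inhibitor of NF-kB signalling, had a log2 fold change of -0.43 ± 0.14. Macrophage genes fell with a median of -0.24 (camera adjusted p = 0.00875; adjusted p = 0.599 with an estimated correlation), and MARCO, a scavenger receptor of macrophages, had 525 ± 144 CPM against 970.0 ± 37.5. That call was lost without MG_OBS 2 (-0.19, adjusted p = 0.198) and CONT 5 (-0.09, adjusted p = 0.535). Without MG_OBS 1 the median was -0.48. Of the 14 macrophage genes 1 was lower when adjusted over the list alone and none over all genes.

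Single genes did not pass in this comparison. edgeR called 0 of 13623 genes, with 1035 at an unadjusted p under 0.05 and a smallest adjusted p of 0.586; DESeq2 called 46 and limma voom 0. In 1714 genes (12.6%) all 3 libraries of one group lay above all 3 of the other, where chance gives 10%. BANK1, a B cell scaffold protein, was among the genes of smallest p, with 20.01 ± 4.74 CPM against 62.9 ± 16.0 (adjusted p = 0.586). The B and plasma cell list as a whole was not called (camera adjusted p = 0.582). Of its 19 members 10 were positive, with a median of 0.15, and 1 was lower adjusted over the list alone. In all, 11 of 23 lists were called, 7 higher and 4 lower, and 6 without CONT 5.

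In the livers of watching birds the proliferation list again rose, with all 31 measured members positive and a median of 1.42 (camera adjusted p = 1.21e-15; adjusted p = 0.814 with an estimated correlation). No member passed, over all genes or adjusted over the list alone. MKI67 had 87.0 ± 99.5 CPM against 30.4 ± 47.9, and the individual values of MKI67 were 202, 27.0 and 32.1 in MG_OBS 1 to 3 and 85.7, 2.77 and 2.69 in CONT 4 to 6. The median was 0.28 without MG_OBS 1, 3.62 without CONT 4, 0.89 without CONT 5 and 0.93 without CONT 6, each past the threshold. Erythroid genes also rose as a list, none of 17 past the test over all genes or adjusted over the list alone, with a median of 1.69 (camera adjusted p = 2.02e-06; adjusted p = 0.814 with an estimated correlation), which became -0.03 without MG_OBS 1, where the call was lost (adjusted p = 0.283), and 3.51 without CONT 4. Thrombocyte genes, markers of the nucleated avian counterpart of platelets, rose with a median of 1.67 in 11 members (camera adjusted p = 1.51e-08; adjusted p = 0.814 with an estimated correlation), 0 of them past the test over all genes or adjusted over the list alone, and lay at 0.56 without MG_OBS 1.

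Cholesterol synthesis genes fell in the livers of watching birds with a median of -0.74 in 20 members (camera adjusted p = 9.03e-05; adjusted p = 0.814 with an estimated correlation), none of which passed, over all genes or adjusted over the list alone. MVD, an enzyme of the mevalonate pathway, had 43.6 ± 15.9 CPM against 95.8 ± 53.4. The call was lost without MG_OBS 1 (-0.35, adjusted p = 0.61) and CONT 5 (-0.03, adjusted p = 0.39), and the median was -0.47 without MG_OBS 2 and -1.60 without MG_OBS 3. Hepatocyte genes fell with a median of -0.53 in 22 members (camera adjusted p = 0.00696; adjusted p = 0.814 with an estimated correlation), again with none past either adjustment, over all genes or adjusted over the list alone. That call was lost without MG_OBS 1 (-0.18, adjusted p = 0.61), where the test turned direction, and without CONT 5 (-0.44) and CONT 6 (-0.15). The hepatocyte median was -1.10 without MG_OBS 2, -0.83 without MG_OBS 3 and -1.01 without CONT 4. In all, 14 of 24 lists were called, but 5 without MG_OBS 1, 4 without CONT 5 and 7 without CONT 6.

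Among single genes edgeR called 0 of 12859 in this liver comparison, with 325 at an unadjusted p under 0.05 and a smallest adjusted p of 1; DESeq2 called 9 and limma voom 0. The groups were separate in 820 genes (6.4%), where chance gives 10%. Without the libraries rich in erythroid transcripts (MG_OBS 1, CONT 4 and MG 8), an alternative chosen after the data were seen, edgeR called 17 genes, 16 higher and 1 lower.

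In the spleens of infected birds, interferon-stimulated genes fell against controls. None of the 18 measured members had a positive fold change, the median was -0.75 (camera adjusted p = 6.73e-33; adjusted p = 0.192 with an estimated correlation), and 16 were lower when adjusted over the list alone, although none passed over all genes. IFIT5, an antiviral protein that binds RNA ends, had 19.5 ± 3.63 CPM against 94.8 ± 31.9 (log2 fold change -2.29 ± 0.29, adjusted p = 0.0521), and DHX58, a sensor of viral RNA, had 13.1 ± 2.70 against 32.6 ± 5.62. The Mx-like gene LOC103815742, whose reads a related copy could share, had 222 ± 13.1 against 551 ± 125 (adjusted p = 0.0521). The individual IFIT5 values were 23.6, 17.9 and 16.9 in MG 7 to 9, of which MG 8 was female and the others male.

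Heterophil and antimicrobial peptide genes, markers of the avian counterpart of neutrophils, rose in the infected spleens with a median of 1.05 in 11 members (camera adjusted p = 3.83e-05; adjusted p = 0.325 with an estimated correlation). Adjusted over the list alone 4 were higher and 1 lower, and none passed over all genes. CSF3R, the receptor of a granulocyte growth factor, had 399.7 ± 19.1 CPM against 167 ± 36.9, and lysozyme LYZ had 429 ± 103 against 62.1 ± 51.7. Glucocorticoid response genes rose with a median of 0.41 in 17 members (camera adjusted p = 2e-05; adjusted p = 0.325 with an estimated correlation), 4 higher and 1 lower adjusted over the list alone and none over all genes. The call was lost without MG 7 and 9 together (0.28, adjusted p = 0.0599) and with sex as a covariate (0.28, adjusted p = 0.183). FKBP5, a co-chaperone induced by glucocorticoids, had 199 and 74.5 CPM in the male libraries MG 7 and 9, 22.9 in the female MG 8 and 14.2 ± 2.80 in controls. CEBPD, which stands in the inflammatory list too, had 203 ± 90.6 against 86.0 ± 13.2.

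Heat shock genes fell in the infected spleens with a median of -0.39 in 17 members (camera adjusted p = 2.23e-06; adjusted p = 0.325 with an estimated correlation), 5 lower and 1 higher adjusted over the list alone and none over all genes. HSPA8, a constitutive chaperone, had 1739 ± 480 CPM against 2877 ± 353. T and NK cell genes fell with a median of -0.33 in 23 members (camera adjusted p = 0.00978; adjusted p = 0.725 with an estimated correlation), 1 of them lower adjusted over the list alone and none over all genes. The call was lost without CONT 6 (-0.11, adjusted p = 0.487), MG 8 (-0.46, adjusted p = 0.0647) or MG 9 (-0.22, adjusted p = 0.138), and with sex as a covariate (-0.16, adjusted p = 0.596), and the median was -0.50 without CONT 5. NOD1, a cytosolic sensor of bacterial peptidoglycan, lay at 86.9 ± 10.5 against 40.4 ± 4.22 (log2 fold change 1.10 ± 0.13, adjusted p = 0.0521).

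In this comparison edgeR called 0 of 13623 genes, with 1268 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0521; DESeq2 called 260 and limma voom 5. The groups were separate in 1930 genes (14.2%), where chance gives 10%. Leaving out the female MG 8 gave 272 calls, of which 146 (53.7%) lay on the Z scaffold, which held 4.75% of tested genes, and 24 were W-type genes; 5 genes were called without MG_OBS 1 and 1 without CONT 4. In all, 9 of 23 lists were called, 2 higher and 7 lower, and 4 without MG 8.

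In the livers of infected birds interferon-stimulated genes fell too, with 1 of 18 members positive and a median of -0.95 (camera adjusted p = 6.7e-15; adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone 4 were lower, and none passed over all genes. CMPK2, a nucleotide kinase induced by interferon, had 7.25 ± 2.63 CPM against 42.8 ± 19.8 (log2 fold change -2.56 ± 0.39, adjusted p = 0.214), and PARP9 had 10.98 ± 1.27 against 30.3 ± 6.04. With MG 8 left as the only MG liver, the median was -0.59. The MHC class II invariant chain CD74, of the antigen presentation list, had 158 ± 30.6 against 574 ± 99.9. That list fell with a median of -0.42 in 11 members (camera adjusted p = 0.0101; adjusted p = 0.131 with an estimated correlation), 1 of them lower adjusted over the list alone and none over all genes. Its call was lost without MG 8 (-0.31, adjusted p = 0.0894), and the median was -0.23 without CONT 5 and -0.23 without MG 9.

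T and NK cell genes fell in the infected livers with a median of -1.40 in 21 members (camera adjusted p = 1.94e-07; adjusted p = 0.369 with an estimated correlation), none of them past the test over all genes or adjusted over the list alone. The call was lost with sex as a covariate (-0.71, adjusted p = 0.0555), and the median was -0.36 without CONT 4. The T cell surface molecule CD2 had 4.34 ± 2.17 CPM against 18.7 ± 10.5. Macrophage genes fell with a median of -0.66 in 14 members (camera adjusted p = 7.57e-05; adjusted p = 0.369 with an estimated correlation), 2 of them lower adjusted over the list alone and none over all genes, and the median was -0.32 without CONT 6. MPEG1, a pore-forming protein of macrophages, had 17.9 ± 2.21 against 43.3 ± 17.1.

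The serum amyloid A-like gene LOC103826772, an acute phase protein that related copies could share reads with, had 3004 ± 2674 CPM in infected livers against 65.3 ± 41.0 in controls (log2 fold change 5.52 ± 1.11, adjusted p = 0.434). Metallothionein-1 (LOC115484025), a metal-binding protein of a family whose copies could share reads, had 715 ± 477 against 5.68 ± 3.06 (6.97 ± 0.94, adjusted p = 0.165). The positive acute phase list was not called over the 7 members matched by symbol, with a median of 0.66 (camera adjusted p = 0.158). It was called over 13 members when those matched by description were added, an alternative chosen after the data were seen (0.66, 11 positive, adjusted p = 0.00235). It was also called without CONT 6 (0.87, adjusted p = 0.0425) and without MG 8 (0.74, adjusted p = 0.0353). Glucocorticoid response genes rose with a median of 0.56 in 19 members (camera adjusted p = 6.29e-04; adjusted p = 0.131 with an estimated correlation), 4 higher and 1 lower adjusted over the list alone and none over all genes. That call was lost without MG 7 and 9 (0.01, adjusted p = 0.0552), and the median was 0.23 without CONT 4, 0.30 without CONT 5 and 0.20 without MG 7. FKBP5 had 190.3 and 98.9 CPM in the male MG 7 and 9 and 18.7 in the female MG 8, against 4.47 ± 3.30 in controls.

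Inflammatory cytokine and NF-kB genes rose in the infected livers with a median of 0.30 in 23 members (camera adjusted p = 0.00459; adjusted p = 0.131 with an estimated correlation), 3 of them higher adjusted over the list alone and none over all genes. SOCS3, an inhibitor of cytokine receptors, had 54.8 ± 15.4 CPM against 5.40 ± 5.17, and NFKBIZ had 67.9 ± 8.79 against 12.2 ± 6.27. The call was lost without MG 8 (0.22, adjusted p = 0.0894), and the median was 0.46 without CONT 4, 0.18 without CONT 5 and 0.15 without CONT 6. Heterophil genes rose with a median of 1.02 in 10 members (camera adjusted p = 1.45e-04; adjusted p = 0.369 with an estimated correlation), 2 of them higher adjusted over the list alone and none over all genes, with medians of 2.25 without CONT 4, 0.46 without CONT 6 and 0.48 without MG 8. The 73 ribosomal protein genes rose with a median of 0.59 (camera adjusted p = 5.08e-17; adjusted p = 0.457 with an estimated correlation), none of them past the test over all genes or adjusted over the list alone, and medians of 0.38 without CONT 4 and 0.93 without CONT 6. The members of smallest p, RPS23 and RPL37, lie on the Z scaffold, of which male birds carry a further copy.

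In the liver of infected birds edgeR called 0 of 12859 genes against controls, with 640 at an unadjusted p under 0.05 and a smallest adjusted p of 0.165; DESeq2 called 65 and limma voom 72. The groups were separate in 1405 genes (10.9%), where chance gives 10%. Without MG 8 edgeR called 32 genes, 21 of them W-type, and without MG_OBS 1 it called 1. In all, 9 of 24 lists were called, and 16 without CONT 4 and 14 without MG 7.

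**Figure D2:**
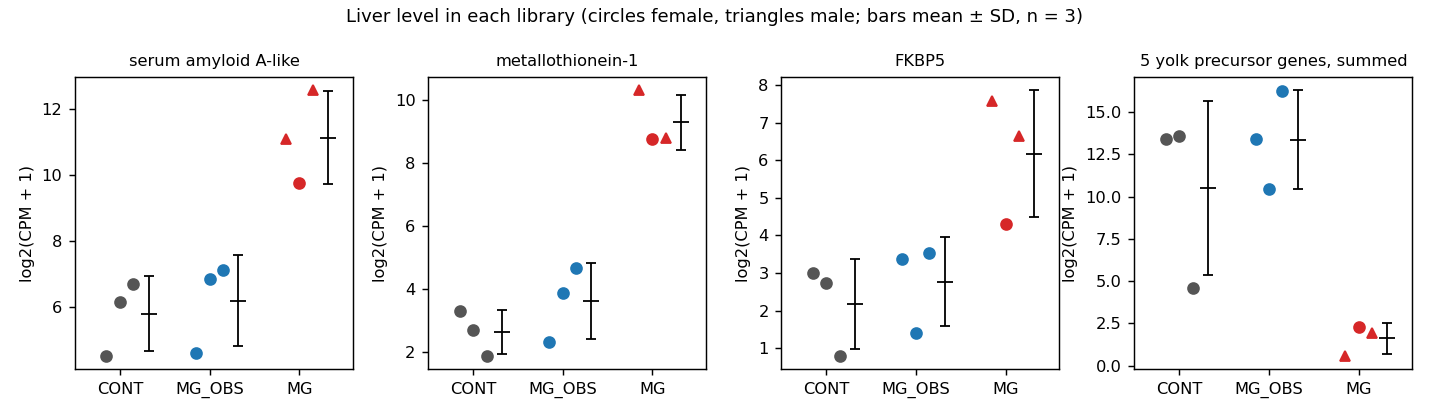
Liver level of 3 genes and of 5 summed yolk precursor genes in each library, as log2(CPM + 1) by treatment; circles are female, triangles male, and bars are mean ± SD (n = 3). Metallothionein-1 (LOC115484025) ran from 432 to 1265 CPM in MG livers and from 2.69 to 24.7 in the others, and the summed yolk precursor genes from 0.512 to 3.91 CPM in MG livers and from 23.2 to 78100 in the others. The yolk precursor values are not TMM-scaled, unlike those of the 3 genes.

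The spleens of watching and infected birds differed in single genes. Of 13623 genes edgeR called 38, of which 19 were higher and 19 lower in watching birds. Interferon-stimulated genes were all higher in the watching birds: the 18 members had a median of 1.01 (camera adjusted p = 8.92e-37; adjusted p = 0.154 with an estimated correlation; fry adjusted p = 0.0207), 5 passed over all genes and 17 adjusted over the list alone. IFIT5 (scaffold NW_022044965.1, 19157115 to 19163043) had 130.2 ± 40.6 CPM against 19.5 ± 3.63 in infected birds (log2 fold change 2.74 ± 0.30, adjusted p = 0.0145). USP18, which removes the ubiquitin-like ISG15 from proteins, had 41.3 ± 13.3 against 5.599 ± 1.61 (2.88 ± 0.33, adjusted p = 0.0145). SAMD9L and DHX58 passed as well, with log2 fold changes of 1.89 ± 0.23 and 1.72 ± 0.20, as did the Mx-like LOC103815742 with 1.52 ± 0.17.

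NOD1, LYZ and CSF3R were lower in the spleens of watching than of infected birds. NOD1 (scaffold NW_022041541.1, 42718226 to 42745986) had 33.0 ± 2.20 CPM against 86.9 ± 10.5 (log2 fold change -1.40 ± 0.13, adjusted p = 0.0145). LYZ had 20.6 ± 12.4 against 429 ± 103 (-4.39 ± 0.67, adjusted p = 0.0491) and CSF3R 154 ± 44.7 against 399.7 ± 19.1 (-1.38 ± 0.22, adjusted p = 0.0412). The heterophil list had a median of -0.36 in 11 members (camera adjusted p = 0.0106; adjusted p = 0.483 with an estimated correlation), 2 of them lower over all genes and 2 higher and 2 lower adjusted over the list alone. Its call was lost without MG_OBS 2 (0.04, adjusted p = 0.208) and MG 8 (-0.24, adjusted p = 0.116), and the median was -0.71 without MG_OBS 1, -0.59 without MG_OBS 3, 0.02 without MG 7 and -0.78 without MG 9. ZBTB16, a transcription factor induced by glucocorticoids, had 11.2 ± 1.96 against 48.3 ± 17.8 (-2.11 ± 0.32, adjusted p = 0.0408). The glucocorticoid response list fell with a median of -0.48 in 17 members (camera adjusted p = 7.89e-06; adjusted p = 0.394 with an estimated correlation), 1 lower over all genes and 6 lower and 1 higher adjusted over the list alone.

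Proliferation genes were higher in the spleens of watching than of infected birds, all 32 of them positive with a median of 1.04 (camera adjusted p = 8.07e-22; adjusted p = 0.394 with an estimated correlation). Adjusted over the list alone 27 passed, and none over all genes. Erythroid genes also rose as a list, none of 17 past the test over all genes or adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.0152; adjusted p = 0.785 with an estimated correlation), a call lost without MG_OBS 1 (0.48), MG 8 (0.51) or MG 9 (0.28), and the median was 0.86 without MG 7. Cholesterol synthesis genes rose with a median of 0.75 in 20 members (camera adjusted p = 8.14e-12; adjusted p = 0.394 with an estimated correlation), 12 of them higher adjusted over the list alone and none over all genes. NSDHL, a sterol dehydrogenase, had 30.4 ± 12.9 CPM against 8.14 ± 1.31 (adjusted p = 0.0682). T and NK cell genes rose with a median of 0.33 in 23 members (camera adjusted p = 2.39e-05; adjusted p = 0.394 with an estimated correlation), 8 higher and 1 lower adjusted over the list alone and none over all genes, and the median was 0.51 without MG 8. Inflammatory cytokine and NF-kB genes fell with a median of -0.23 in 24 members (camera adjusted p = 5.79e-04; adjusted p = 0.394 with an estimated correlation), 6 of them lower adjusted over the list alone and none over all genes, with medians of -0.39 without MG_OBS 2, -0.14 without MG_OBS 3 and -0.35 without MG 7.

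The 38 calls depended on single libraries. edgeR called 0 genes without MG 9, 9 without MG_OBS 3, 17 without CONT 5, 18 without MG 7, 21 without MG_OBS 1 and 429 without MG 8, of which 166 lay on the Z scaffold. With sex as a covariate it called 0. DESeq2 called 853 genes and limma voom 264; 2284 genes had an unadjusted p under 0.05. The groups were separate in 2964 genes (21.8%), where chance gives 10%. Of the 38 genes 2 lay on the Z scaffold, LIFR among them, and 9 of 23 lists were called, 6 higher and 3 lower.

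**Figure D3:**
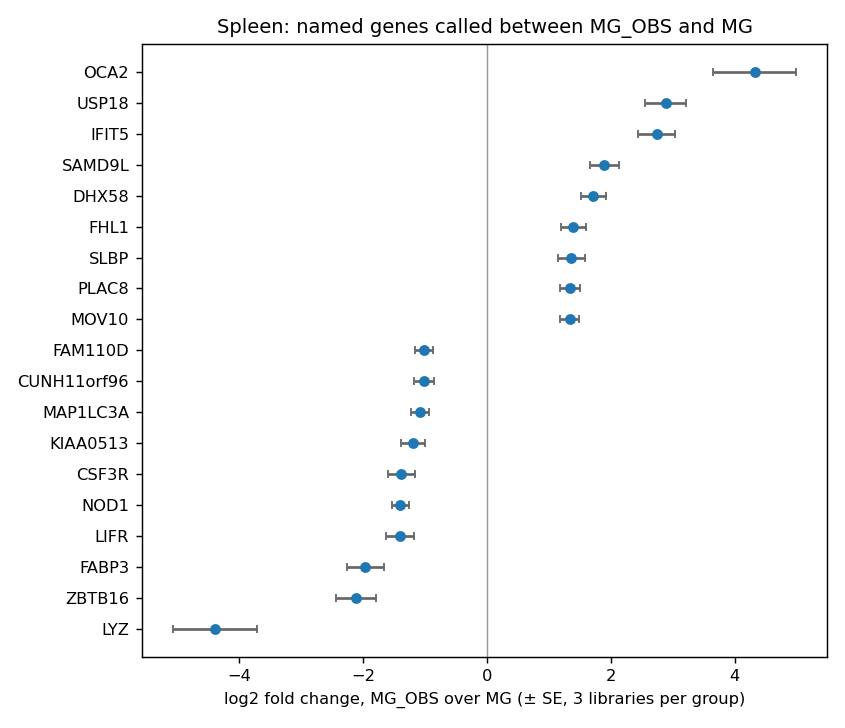
Log2 fold change (horizontal axis) of 19 named genes called between MG_OBS and MG spleens, with bars of ± SE from 3 libraries per group. Estimates run from 4.32 for OCA2 to -4.39 for LYZ, and the interferon-stimulated USP18, IFIT5, SAMD9L and DHX58 lie between 1.72 and 2.88.

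In liver, watching birds also had higher interferon-stimulated genes than infected birds, with 17 of 18 members positive and a median of 1.55 (camera adjusted p = 8.61e-21; adjusted p = 0.0932 with an estimated correlation; fry adjusted p = 0.021). Adjusted over the list alone 14 were higher, and none passed over all genes. CMPK2 had 54.7 ± 4.40 CPM against 7.25 ± 2.63 (log2 fold change 2.91 ± 0.40, adjusted p = 0.116), and the OAS1-like gene LOC103824282, which related copies could share reads with, 85.3 ± 51.4 against 5.04 ± 4.32. T and NK cell genes rose beside them, 21 of 21 positive with a median of 0.85 (camera adjusted p = 4.77e-05; adjusted p = 0.545 with an estimated correlation) and none past the test over all genes or adjusted over the list alone. That call was lost in the fits that rest on MG 8 alone for MG, with sex as a covariate (0.32) and without MG 7 and 9 (0.30). The T and NK cell median was 1.31 without MG 8. Macrophage genes rose with a median of 0.91 in 14 members (camera adjusted p = 1.38e-04; adjusted p = 0.545 with an estimated correlation), 2 of them higher adjusted over the list alone and none over all genes. Proliferation genes rose with all 31 members positive and a median of 1.56 (camera adjusted p = 9.08e-10; adjusted p = 0.545 with an estimated correlation), none past the test over all genes or adjusted over the list alone. That median was 0.60 without MG_OBS 1 and 3.15 without MG 8, and the call was lost without MG 7 and 9 (0.51, adjusted p = 0.316) and with sex as a covariate (0.49, adjusted p = 0.414). Erythroid genes also rose, with a median of 1.36 (camera adjusted p = 0.00776; adjusted p = 0.553 with an estimated correlation), and thrombocyte genes at 0.96 (camera adjusted p = 0.00374; adjusted p = 0.553 with an estimated correlation), none of either list past the test over all genes or adjusted over the list alone. The erythroid call was lost without MG_OBS 1 (-0.29, adjusted p = 0.869), without MG 9 (0.97, adjusted p = 0.0631), with sex as a covariate (0.62, adjusted p = 0.999) and without MG 7 and 9 (0.62, adjusted p = 0.98). The erythroid median was 2.58 without MG 8. The thrombocyte call was lost without MG_OBS 1 (0.13, adjusted p = 0.48), with sex as a covariate (0.07, adjusted p = 0.97) and without MG 7 and 9 (0.07, adjusted p = 0.98), where the test turned direction. The thrombocyte median was 1.91 without MG 8 and 0.61 without MG 9.

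Complement genes fell in the watching livers against infected ones as a list, with 9 of 22 members positive and a median of -0.80 (camera adjusted p = 0.0226; adjusted p = 0.553 with an estimated correlation), none past the test over all genes or adjusted over the list alone. The call was lost without MG_OBS 1 (-0.46, adjusted p = 0.48), without MG 7 (-0.40, adjusted p = 0.0622), with sex as a covariate (-0.16, adjusted p = 0.492) and without Z scaffold and W-type genes (-0.79, adjusted p = 0.075). The complement median was -0.51 without MG_OBS 2 and -0.47 without MG 9. C9, the pore-forming complement component, which lies on the Z scaffold, had 189 ± 152 CPM against 2260 ± 1557 (log2 fold change -3.58 ± 1.23, adjusted p = 0.536), and the fibrinogen chain FGB 1025 ± 654 against 4296 ± 2561 (adjusted p = 0.684). The positive acute phase list fell with a median of -1.56 in 7 members (camera adjusted p = 0.00374; adjusted p = 0.545 with an estimated correlation), none past the test over all genes or adjusted over the list alone. Its call was lost without MG_OBS 1 (-0.74, adjusted p = 0.48), without MG 7 (-0.99, adjusted p = 0.0901) and with sex as a covariate (0.09, adjusted p = 0.887), and the median was -0.87 without MG 9. Against controls, the complement median was -0.65 in watching livers (camera adjusted p = 0.0216, and 0.814 with an estimated correlation). It ranged from -1.10 to -0.05 with a library left out. In infected livers it was 0.23, not called. The positive acute phase median was -0.77 in watching livers (camera adjusted p = 0.032, and 0.814 with an estimated correlation) and -0.26 without MG_OBS 1. In infected livers it was 0.66, not called. Hepatocyte genes were lower in watching than in infected livers. Their median was -0.76 in 22 members (camera adjusted p = 0.001, and 0.553 with an estimated correlation), none past the test over all genes or adjusted over the list alone. Their call was lost without MG_OBS 1 (-0.24, adjusted p = 0.564), the direction turned with sex as a covariate (0.22, adjusted p = 0.737) and without MG 7 and 9 (0.18, adjusted p = 0.91). The hepatocyte median was -1.21 without MG_OBS 2 and -1.16 without MG 8. The edgeR test called 0 of 12859 genes between these livers, with 986 at an unadjusted p under 0.05 and a smallest adjusted p of 0.116; DESeq2 called 167 and limma voom 55. The groups were separate in 1656 genes (12.9%), where chance gives 10%. Without MG 8 edgeR called 37 genes, 22 of them W-type, and without CONT 6 it called 1. In all, 15 of 24 lists were called, and 6 without MG_OBS 1.

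For 2 genes edgeR called a difference between the tissues in the response to infection. Metallothionein-1 (LOC115484025, scaffold NW_022041875.1, 8172895 to 8174329) had 6.11 ± 2.46 CPM in infected spleens and 6.57 ± 2.79 in control spleens, so that the log2 fold change in spleen lay 7.03 ± 0.90 below that in liver (-7.03, adjusted p = 0.0116). SHOC2, a scaffold protein of the RAS pathway (scaffold NW_022044965.1, 26353519 to 26415209), had 52.8 ± 17.0 CPM in infected and 10.4 ± 1.98 in control livers, and 45.1 ± 5.38 and 47.4 ± 5.42 in spleens (difference -2.37 ± 0.35, adjusted p = 0.0326). edgeR called 0 of the 2 genes without liver CONT 5, liver CONT 6, spleen MG 7 or spleen MG 8, and 0 with sex as a covariate. It called 1 without liver CONT 4, liver MG 7, liver MG 8, any spleen MG_OBS library, any spleen CONT library or spleen MG 9. With liver and spleen blocked by library number, a pairing that the labels do not state, it called 0. At an unadjusted p under 0.05 there were 722 of 14334 genes; DESeq2 called 40 and limma voom 5.

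For the watching birds edgeR called 0 of 14334 genes as differing between the tissues, with 598 at an unadjusted p under 0.05 and a smallest adjusted p of 0.693; DESeq2 called 24 and limma voom 0. It called 1 without liver MG_OBS 1 and 2 without liver MG_OBS 3. The cholesterol synthesis list differed, with a median difference of 1.28 between spleen and liver (camera adjusted p = 1.58e-07; adjusted p = 0.727 with an estimated correlation). The interferon-stimulated list was not called as differing between the tissues, for watching birds (-0.14, camera adjusted p = 0.22) or for infected birds (0.05, camera adjusted p = 0.616).

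The responses of watching and infected birds correlated less than those of simulated unchanged groups. The simulation drew each gene on its own, so its spread leaves out variation that genes share and cannot test this difference. Across 12859 genes in liver the log2 fold changes of both groups against controls correlated at r = 0.208. Simulated unchanged groups with simulated controls in common gave 0.501 on average over 100 draws. The covariance was 0.119 against 0.311 (difference -0.19). In spleen r was 0.283 against 0.505 over 13623 genes, with a covariance of 0.0659 against 0.0915 (difference -0.03). The liver r was 0.0645 without MG 8, 0.522 without CONT 4 and 0.343 without CONT 6 (simulated 0.448, 0.603 and 0.595). The spleen r was 0.429 without CONT 4 and 0.444 without CONT 5 (simulated 0.606 and 0.615). Over genes with a mean log2 CPM of at least 3, r was 0.097 in liver and 0.116 in spleen (simulated 0.501 and 0.497). Genes are not independent replicates, and 3 controls cannot be split into parts of at least 2. Without liver libraries 1, 4 and 8 the liver difference was -0.095. The liver difference was 0.04 without CONT 4 and -0.34 without CONT 5; the spleen difference was -0.01 without MG_OBS 2, -0.01 without CONT 4, -0.01 without MG 8 and -0.00251 without MG 9. The last lay within the SD of its simulated draws, 0.00317, a spread that also leaves out variation shared by genes. No gene was called in either group against controls, so 0 calls were shared.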

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

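The tests of sex on the interferon-stimulated and yolk precursor genes, of T and NK cells in both tissues and of a single library in liver were chosen only after the result was seen. With groups of 3, no library was tested for standing apart from its group.

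A difference between the tissues, tested as an interaction, singled out 2 genes for infected birds and several lists. The spleen fold change of metallothionein-1 (LOC115484025) lay at -7.03 relative to liver and that of SHOC2 at -2.37. Of 100 splits of the libraries within each tissue, the real one included, 8 gave as many calls (real 2, highest other 2), so chance was not excluded. For watching birds the real count was 0 (highest other 6), which every split reaches, so that the 100 of 100 tests nothing.

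For watching birds, camera singled out 13 lists, none of them with an estimated correlation (adjusted p = 0.727 each). The median spleen minus liver difference was 2.81 for positive acute phase, 2.05 for negative acute phase, 1.36 for hepatocyte, 1.28 for cholesterol synthesis, 0.82 for complement, 0.82 for T and NK cell, 0.78 for unfolded protein response, 0.73 for lipogenesis and 0.50 for fatty acid oxidation genes. It was -1.10 for erythroid, -0.84 for thrombocyte, -0.31 for proliferation and -0.29 for ribosomal protein genes. Many acute phase and hepatocyte genes were too low in spleen for the filter there. It kept 10 hepatocyte and 5 negative acute phase genes (22 and 8 in liver) and too few positive acute phase genes for a test. With description matches the positive acute phase median was -0.60 in spleen (8 members) and -0.61 in liver (13), so its difference of 2.81 is not reliable. For infected birds the medians were 1.13 for T and NK cell (adjusted p = 0.578 with an estimated correlation), 0.94 for macrophage (0.527), 0.40 for circadian clock (0.36) and -0.64 for ribosomal protein genes (0.527).

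Interferon-stimulated genes lay lower in infected than in control birds in both tissues. Against a smaller share of T and NK cells as the whole cause in spleen, the T and NK cell list lay 0.42 above the interferon-stimulated list (95% bootstrap interval over list members 0.15 to 1.11). Genes were resampled, not libraries, so the interval leaves out the spread between libraries. With a library left out, the spleen median ran from -0.495 to -0.114 for T and NK cell and from -0.902 to -0.677 for interferon-stimulated genes. In liver the difference was -0.45 (95% bootstrap interval over list members -0.81 to 0.27), so fewer such cells stay a possible explanation there, although without CONT 4 the T and NK cell median of -0.36 lay above the interferon-stimulated median of -1.04. Sex stays open: in the female MG 8 the list lay at -0.54 in liver and -0.75 in spleen relative to the control mean, but that is 1 library per tissue. Infection itself was not tested apart from sex and collection, and stays open as a hypothesis.

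Proliferation genes lay higher in watching birds than in controls. In spleen a single library does not account for it, since the lowest median with any library left out was 0.76, without CONT 6. In liver the median fell to 0.28 without MG_OBS 1, so a large share from that library stays possible. It rose to 3.62 without CONT 4, so single libraries moved it both ways. The list level ran from 1.02 to 3.45 in watching livers and from -1.33 to 2.30 in control livers. Erythroid precursors, which divide, stay open in both tissues: with the erythroid score as a covariate the median was 0.79 in spleen (0.41 to 0.95 with a library left out) against 0.99 without it, and 0.51 in liver (0.03 to 1.05) against 1.42. A response to watching sick birds stays open as well and was not tested apart from these.

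Yolk precursor genes, 5 found by description after the data were seen, were nearly silent in infected livers, at 0.512, 3.91 and 2.88 CPM in MG 7, 8 and 9, against 23.2 to 78100 CPM in the others. Males make no yolk, so sex may account for MG 7 and 9. It does not apply to the female MG 8, whose 3.91 CPM lay under the 23.2 of the lowest control, CONT 6. With controls ranging from 23.2 to 12160 CPM, a female out of laying condition stays as open as an effect of infection.

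With 3 libraries against 3 there are 10 splits, the real one included, too few for a share under 0.05. Gene calls as many as the real ones came in 10 of 10 splits for liver MG_OBS against CONT (real 0, highest other 1), 10 for liver MG against CONT (0, 0) and 10 for liver MG_OBS against MG (0, 2). In spleen they came in 10 (0, 0), 10 (0, 0) and 1 (38, 1) for the same comparisons. A real count of 0 is reached by every split, so those 10 of 10 test nothing. List calls as many as the real ones came in 5 (14, 15), 5 (9, 18) and 3 (15, 16) splits in liver and in 4 (11, 11), 4 (9, 10) and 6 (9, 11) in spleen.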

How the results depend on the processing

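The alternatives without robust estimation, without liver libraries 1, 4 and 8, without libraries 7 and 9, and lists with description matches were chosen after seeing the data. Comparisons are given in the order watching against control, infected against control, watching against infected, with main counts of 0, 0 and 0 genes and 14, 9 and 15 lists in liver and 0, 0 and 38 genes and 11, 9 and 9 lists in spleen. Where a result changed, the cause was not tested.

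DESeq2 called 9, 65 and 167 genes in liver, 46, 260 and 853 in spleen, and 24 and 40 interactions (main 0 and 2). Limma voom called 72 and 55 in the liver comparisons with MG, 5 and 264 in the spleen ones and 5 interactions for MG. A fit over all libraries called 31 and 193 genes in the liver comparisons with MG, 3 in spleen MG_OBS against MG, and 7 lists in liver MG_OBS against CONT, and gave the spleen complement list 0.003 for MG_OBS against CONT. Fitting only the groups compared left 8 genes in spleen MG_OBS against MG and 1 interaction for MG. No filter called 7 genes in spleen MG against CONT, and moved the shared spleen response from -0.03 to -0.006. At an adjusted p under 0.1, 9 and 202 genes were called in the spleen comparisons with MG, and with a fold threshold of 1.2, which gives no list tests, 12 in spleen MG_OBS against MG. Camera with an estimated correlation called 0 lists in all 6 comparisons; fry called 0, 1 and 2 in liver and 0, 0 and 1 in spleen.

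With sex as a covariate, 15 and 8 lists were called in the liver comparisons with MG, 0 genes in spleen MG_OBS against MG and 0 interactions for MG. Without libraries 7 and 9 the counts were 15 and 8 lists in liver, 15 lists and 1 gene in spleen MG_OBS against MG, and 0 interactions for MG, and the shared response was -0.071 in liver and -0.01 in spleen. Reversed list medians under the covariate and without 7 and 9 were, in liver MG_OBS against MG, cholesterol synthesis 1.194 and 1.193, fatty acid oxidation 0.591 and 0.591, hepatocyte 0.216 and 0.183, lipogenesis 1.216 and 1.216, negative acute phase 0.433 and 0.433, thrombocyte 0.073 and 0.072, and positive acute phase 0.106 without 7 and 9. In liver MG against CONT they were hepatocyte -0.809 and -0.781 and proliferation 0.875 and 0.83; in spleen, complement 0.379 and 0.368 for MG_OBS against MG, and proliferation 0.193 for MG against CONT without 7 and 9. The covariate and the fit without 7 and 9 both leave the female MG 8 as the only library behind the effect of MG. They are close to the same comparison and cannot tell sex from that library. Without liver libraries 1, 4 and 8, 17, 56 and 74 liver genes and 10 interactions for MG_OBS were called, and liver proliferation was 0.427 for MG against CONT.

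Leaving out 1 library at a time, gene calls ranged over 0 to 0, 0 to 32 and 0 to 37 in liver, 0 to 0, 0 to 272 and 0 to 429 in spleen, and 0 to 2 and 0 to 2 for the interactions. List calls ranged over 4 to 14, 8 to 16 and 6 to 17 in liver and 6 to 11, 4 to 9 and 7 to 12 in spleen. The shared response ran from -0.338 to 0.044 in liver, reversed without CONT 4, and from -0.037 to -0.003 in spleen. Lists that reversed with a library left out, with their ranges, follow. In liver MG_OBS against CONT they were, without MG_OBS 1, fatty acid oxidation 0.022 (-0.711 to 0.022), hepatocyte -0.176 (-1.103 to -0.15), negative acute phase -0.331 (-1.412 to -0.132) and positive acute phase -0.261 (-1.239 to -0.261), where median and test differ in sign for the negative ones. Ribosomal protein reversed at -0.136 without MG_OBS 2 and -0.077 without CONT 4 (-0.136 to 0.474), and T and NK cell at 0.536 without CONT 4 (-0.737 to 0.536). In liver MG against CONT, proliferation was 1.942 without CONT 4 and 0.102 without MG 7 (-1.909 to 1.942), and stroma and muscle -0.744 without MG 8 (-0.744 to 0.593). In spleen, unfolded protein response reversed without MG_OBS 3 for MG_OBS against CONT (-0.084 to 0.508) and against MG (-0.144 to 0.464). For spleen MG against CONT, proliferation was 0.248 without CONT 4 (-0.302 to 0.248) and stroma and muscle -0.077 without MG 8 (-0.483 to -0.077), again with a test of the other sign.

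By the labels, liver and spleen libraries share only a number. In the data same-numbered libraries also had the same sex, with 7 and 9 male in both tissues. Same-numbered pairs correlated at 0.036 to 0.276, 6 of 9 over 0.1, and 7 of 9 matched their own number best, a hint from the data, not the design. With the replicate block, 0 interactions were called for MG and 0 for MG_OBS.

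Of the named genes called, 343 values kept their call and 205 lost it over the alternatives, and none reversed. Of called lists, 1370 values kept it, 303 lost it and 15 reversed; of lists not called, 1712 stayed so, 126 passed and 21 reversed. Depth was at least 13030732 counts in each library; what it limits was not tested apart from the spread between libraries (biological coefficient of variation 0.607 in liver and 0.293 in spleen).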

Other observations

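Egg yolk precursor genes varied widely among female livers. The 5 genes summed to 10980, 1374 and 78100 CPM in MG_OBS 1 to 3 and to 10760, 12160 and 23.2 CPM in CONT 4 to 6. GREB1, an estrogen-induced gene chosen after its values were seen, had 840, 13 and 754 counts in MG_OBS and 443, 81 and 0 in CONT livers, and 0, 7 and 4 in MG 7 to 9. The progesterone receptor PGR, of the same list, did not follow it. PGR had 22, 114 and 128 counts in MG_OBS, 60, 90 and 73 in CONT and 74, 17 and 8 in MG livers. The estrogen receptor ESR1 had 999, 773 and 1240, then 1031, 1598 and 561, then 257, 433 and 399 in the same order.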
